A study of Homo sapiens with 18 samples.

How the data were processed

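Poly(A)-enriched RNA from SJSA-1 cells was sequenced in 18 libraries, 3 for each of 6 groups. Cells received DMSO or 1 µg/mL NCS for 72 h, the first 48 h before the compound, and DMSO, 1 µM MI-1061 or 1 µM MD-224 for the last 24 h. The treatment label of some libraries writes the inhibitor's name with other digits than their titles, and the titles were followed.

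The table holds normalized counts as the authors deposited them (unit: signal), that is, read counts divided by a size factor per library. The submitters' notes name HISAT2 2.0.5.2, featureCounts 1.6.3, DESeq2 2.11.40.6 and the genome build GRCh38, without saying what each did. In 13 libraries every value of up to 2000 reads was a whole multiple of 1 step (tolerance 0.01 reads), so read counts could be recovered, with size factors of 0.651 to 1.55. Larger values were not checked and were rounded to the nearest read, so their counts are approximate. In the other 5 libraries the step of 1 read was not recovered, so tests on counts were run on the 9 libraries without NCS alone. The table lists 3074 genes, each at least 1.75-fold higher in the mean of NCS with MI-1061 than in that of DMSO. In 3028 of them all 3 libraries with NCS and MI-1061 lay above all 3 with DMSO. The listing itself favours this, so a chance share is no baseline for it. The table is a selection of genes, so its sums are not depths and its counts of higher genes are conditioned on the selection. Of the names 2781 were current symbols, 2795 matched a RefSeq symbol, 213 a RefSeq synonym only and 66 neither. Coordinates are from RefSeq for GRCh38.p14.

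The groups, comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Values were used as log2(value + 1), with genes of at least 10 in at least 3 libraries (3073 tested, 1 below), in limma 3.58.1 with a trended variance and all 6 groups in 1 fit (R 4.3.3). Adjusted p values are Benjamini-Hochberg over the tested genes of a comparison, with calls under 0.05, and tests are two-sided unless stated. Fold changes are 2 to the power of the limma estimate. There were 7 pairwise comparisons and 2 interactions, each the response to a compound after NCS minus that without NCS. EdgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on recovered reads for the 3 comparisons without NCS. Gene lists numbered 23, of which 12 had at least 5 listed members and were tested by camera with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The 5 lists with no listed gene were RNA polymerase III transcripts, mitosis, DNA replication, homologous recombination with Fanconi repair, and mitochondrially encoded genes. Their absence from a selection of genes in poly(A) RNA does not show whether they were detected or how they changed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

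Whether replicate numbers pair libraries was checked by correlating residuals of like-numbered libraries. By a cut on the lowest correlation they were called paired in 6 pairwise comparisons (lowest correlation 0.102 to 0.215). They were not in NCS against DMSO (0.0627 to 0.297) or in the interactions (0.0197 to 0.399 and −0.0196 to 0.472). The cut is arbitrary: NCS against DMSO missed it through replicate 3 alone, with 0.286 and 0.297 for replicates 1 and 2. The main fit left the replicate number out. These correlations are across genes, which are not independent replicates. The block on the replicate number is given where it changes a call or moves a count by more than 1.5 times. Replicates of a group had Pearson correlations of 0.9636 to 0.9921 across genes, and the chi-square per gene between 11 pairs of replicates with recovered reads was 38.35 to 133.5. Abundant genes dominate that mean, so it does not show how much counting error adds for genes with low counts.

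The genes always considered were MDM2, MDM4, CDKN1A, IFNB1, RIGI, CXCL10, CCL5, ISG15, POLR3A and POLR3G, of which MDM2, CDKN1A and ISG15 were listed. A further gene of this rule is not reported here. Each pairwise comparison added the 8 largest rises and 8 largest falls with an adjusted p under 0.05, a mean of at least 50, a current symbol and no overlap of the 3 and 3 libraries. Each interaction added 5 genes in each direction. Up to 4 members of each list with the smallest p were added. This gave 187 genes, and the text names part of them. Genes of the lists for lysosome, stratified epithelium and striated muscle were chosen after the data were seen.

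The test was tried on simulated data with 200 of 3073 genes changed. In NCS against DMSO limma recovered 81.8%, 31.3% and 7.46% of genes changed 4-, 2- and 1.5-fold, with 9 false calls. In MD-224 after NCS it recovered 80.3%, 29.9% and 7.46%, with 6 false calls, and in the interaction of NCS and MD-224 60.6%, 7.46% and 4.48%, with 4. EdgeR recovered 78.8%, 25.4% and 11.9% with 4 false calls, and DESeq2 84.8%, 47.8% and 19.4% with 12. On limma's fit, camera called a shifted list and 0 of 20 unshifted lists. The simulated genes varied independently, so this does not test camera on correlated genes. In the simulated data changes under 2-fold were often missed. With more genes changed the adjusted threshold is less strict, so these shares do not carry over to the comparisons here. With NCS 1659 genes were called higher, and 866 of them were at least 2-fold higher.

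Alternatives were a pseudocount of 0.5 or 5, no filter, a mean of at least 50, TMM scaling from edgeR, the replicate block, only the compared groups in the fit, edgeR and DESeq2, and leaving out each library and each replicate number. TMM was computed on the listed genes, so it takes out a rise that most of them share.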

Results

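Poly(A) RNA was sequenced from SJSA-1, a human osteosarcoma cell line with an amplified MDM2 gene. Cells were kept for 72 h with vehicle (DMSO) or with 1 µg/mL neocarzinostatin (NCS), a drug that breaks DNA. In the last 24 h they also received DMSO, the MDM2 inhibitor MI-1061 or the MDM2 degrader MD-224, each compound at 1 µM. The 6 groups held 3 libraries each. MDM2 encodes a ubiquitin ligase, and the series title also names RNA polymerase III and the response to cytosolic DNA. The table used here lists 3074 genes, whose normalized counts summed to between 4594460 and 17252590 per library. In the 13 libraries where reads could be recovered, the listed genes held about 4490870 to 10535849 reads. Every listed gene had a mean at least 1.75-fold higher with NCS and MI-1061 together than with DMSO (median 3-fold). The counts below therefore say which of these genes each treatment changed. Genes that NCS with MI-1061 left unchanged or lowered are not analysed here, and a sum over listed genes is not a sequencing depth. Members of a gene list are called measured where the table holds them, so counts of members that rose are conditioned on the listing. Absent members may have been detected without such a rise. Of the 3073 tested genes limma called 54% higher with NCS, 67.6% with MI-1061 and 39.9% with MD-224. After NCS the shares were 70.5% with MI-1061 and 15.1% with MD-224.

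MDM2 itself (chromosome 12, 68808172 to 68850686, GRCh38.p14) was the most abundant response gene. Its mean normalized count was 135100 ± 25700 (SD, n = 3) with DMSO, 1572000 ± 337000 with MI-1061 and 407800 ± 63800 with MD-224. After NCS it was 182300 ± 5970 without a compound, 2460000 ± 76700 with MI-1061 and 832800 ± 132000 with MD-224. MDM2 held 2.87% ± 0.612 of the listed counts with DMSO, 14.1% ± 2.28 with MI-1061 and 14.4% ± 0.475 with NCS and MI-1061. CDKN1A (chromosome 6, 36676463 to 36687332), which encodes the cell-cycle inhibitor p21, went from 11840 ± 1580 with DMSO to 354700 ± 9040 with MI-1061, 90720 ± 11500 with MD-224, 64570 ± 5310 with NCS, 712600 ± 53200 with NCS and MI-1061 and 312000 ± 87600 with NCS and MD-224. GDF15, a stress cytokine and p53 target, was at 22047 in DMSO replicate 2 and at 4563.3 and 3939.8 in replicates 1 and 3, so that library stood apart for this gene.

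**Figure D1:**
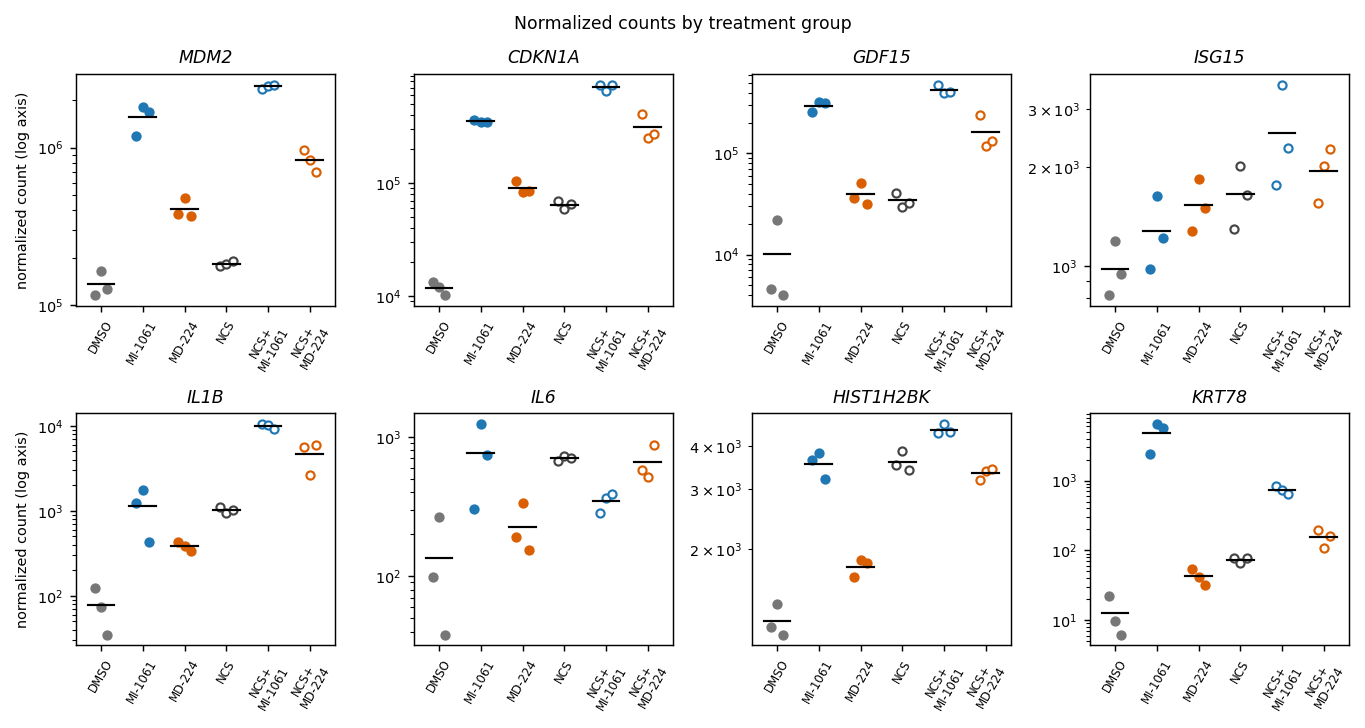
Normalized counts (log axis) of 8 genes in the 18 libraries; each point is a library, each line a group mean, filled points are libraries without NCS and open points libraries with NCS. MDM2 and CDKN1A were highest with NCS and MI-1061, at means of 2460000 and 712600, and KRT78 was highest with MI-1061 alone, at 4847.

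The comparison of NCS with DMSO asks what 72 h with NCS alone did to these genes. DNA damage itself was not measured here. Among the largest rises were TREM1 and C3. TREM1, a receptor that amplifies inflammatory signals, rose 34.7-fold (log2 5.12, SE 0.37; limma adjusted p = 6.85e-08), C3, the central component of complement, 19.4-fold (adjusted p = 3.78e-05), and SERPINB2, a plasminogen activator inhibitor, 19.1-fold (adjusted p = 0.00019). MMP3, a matrix-degrading protease, rose 16.9-fold, and the cytokine gene IL1B rose 14.8-fold (adjusted p = 3.69e-06). Some of these folds rest on single DMSO libraries: the log2 of C3 (4.28) was 4.95 without replicate 2, that of MMP3 (4.08) was 4.72 without replicate 1, and that of SERPINB2 (4.25) was 5.31 without replicate 1 and 3.65 without replicate 3. With a pseudocount of 5 the log2 of TREM1 was 4.31. CDKN1A rose 5.47-fold (log2 2.45, SE 0.16; adjusted p = 3.36e-08). Among the genes that fell were FGFR2, a growth factor receptor (0.369-fold), E2F7, a repressor of cell-cycle genes (0.452-fold), PSAT1, an enzyme of serine synthesis (0.457-fold), and RAD51C, a recombination protein (0.52-fold).

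Of 28 cytokine and chemokine genes on the list, 8 were in the table. Of these 7 rose with NCS, and the median of the 8 was 7.87-fold. IL1A rose 6.53-fold, CXCL1 10.4-fold and IL6 6.92-fold (log2 2.79, but 3.49 without DMSO replicate 2 and 2.10 without DMSO replicate 3). The list rose more than other listed genes by camera (adjusted p = 0.0378), but not with an estimated correlation (adjusted p = 0.565), nor with the replicate number as a block (0.0986), with a mean of at least 50 (0.0592), without DMSO replicate 1 (0.0584) without NCS replicate 1 (0.056) or without replicate 1 of every group (0.0899). Secreted proteases and growth factors rose in 13 of 15 measured members, 14 when adjusted over the list alone, and examples were SERPINE2 (2.73-fold) and PLAT, the tissue plasminogen activator (log2 1.08). That list had an adjusted p of 0.00877 by camera and an adjusted p of 0.628 with an estimated correlation. All 8 measured NF-kB pathway genes rose, among them TRAF1 at 4.05-fold, with an adjusted p of 0.142 by camera. With TMM scaling 1 NF-kB pathway gene, 6 cytokine genes and 10 genes of the secreted list rose and 0 fell. Replication-dependent histone transcripts, which usually end without a poly(A) tail, rose in 17 of 18 measured members with a median of 4.15-fold, and in 14 with TMM scaling. HIST1H4H rose 7.77-fold, HIST1H2BG 7.9-fold and HIST1H2BK 2.94-fold, and the list had an adjusted p of 5.45e-06 by camera and an adjusted p of 0.172 with an estimated correlation. Their near-identical copies make single histone values uncertain.

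The p53 targets were 35 of the 38 genes on that list, and 25 of them rose with NCS while 0 fell, with a median of 1.55-fold; with TMM scaling 6 rose, 8 fell and the median log2 was 0.02. Besides CDKN1A, TP53INP1 (3.61-fold), a regulator of autophagy, and SPATA18 (3.47-fold), which acts in mitochondrial quality control, rose. The p53 list did not pass camera (adjusted p = 0.208, and 0.87 with an estimated correlation), but had an adjusted p of 0.0453 without DMSO replicate 2. MDM2 rose 1.36-fold (adjusted p = 0.031), and with TMM scaling its log2 change was −0.17. The MDM2 call was lost without DMSO replicate 1 (adjusted p = 0.121), DMSO replicate 3 (0.0857), NCS replicate 1 (0.0551), NCS replicate 2 (0.0644) or NCS replicate 3 (0.0808), and without replicate 1 (0.0807) or 3 (0.226) of every group. The 3 measured haematopoietic cell markers rose too, ITGAM 6.95-fold, CD68 3.61-fold and LAPTM5 2.47-fold. The LAPTM5 call was lost with TMM scaling (adjusted p = 0.145) and without replicate 3 of every group (0.0709), and the log2 of ITGAM (2.80) was 2.17 without DMSO replicate 3.

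In all, 1659 of 3073 genes were higher with NCS and 40 lower by limma, and 456 higher and 467 lower with TMM scaling, which moved the median log2 of all genes by −0.60. TMM assumes that most listed genes do not change, which this table does not offer. Without replicate 3 of every group, 902 genes were called in place of 1699. The DMSO libraries are among those by which the genes are listed, so these counts depend on the listing.

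MI-1061 without NCS was compared with DMSO to show what the inhibitor did in cells not given NCS. The largest rises were in genes with low counts in DMSO, such as KRT78 with a mean of 12.54. KRT78 and KRT4, keratins of stratified epithelia, rose 369-fold (log2 8.53, SE 0.40; limma adjusted p = 4.01e-11) and 225-fold (adjusted p = 1.73e-12). TBX4, a transcription factor of limb development, rose 161-fold, the phosphodiesterase gene PDE4C 159-fold, and TNFRSF10A, a death receptor, 131-fold. With a pseudocount of 5 the log2 of PDE4C, TBX4 and TNFRSF10A (7.31, 7.33 and 7.04) was 6.70, 6.49 and 5.798, and without replicate 1 of every group that of KRT78 and TBX4 was 9.45 and 7.96. Genes that fell included CHMP4C, an ESCRT-III subunit (0.218-fold), the homeobox gene NKX2-8 (0.302-fold) and NEMP2, which encodes a nuclear envelope protein (0.351-fold).

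The p53 targets rose as a group: 34 of 35 passed and 0 fell, with a median of 5.62-fold, and with TMM scaling 34 rose and 1 fell. MDM2 rose 11.6-fold (log2 3.53, SE 0.17; adjusted p = 4.01e-11), CDKN1A 30.1-fold, the death receptor gene FAS 9.78-fold and TP53INP1 11-fold. Camera gave the list an adjusted p of 7.48e-11, and an adjusted p of 0.716 with an estimated correlation. Immediate early and MAPK feedback genes rose in 11 of 12 measured members, 12 when adjusted over the list alone, led by FOSB, an AP-1 subunit, at 11.5-fold (camera adjusted p = 0.642). All 8 measured NF-kB pathway genes rose, with NFKBIZ at 2.9-fold, and 17 of 18 histone transcripts rose, with HIST1H2BJ at 7.74-fold (camera adjusted p = 0.0767, and 0.0336 and 0.0418 without DMSO replicate 2 and without MI-1061 replicate 3, 0.0492 without replicate 3 of every group, 0.0105 with TMM scaling and 0.0268 with only the compared groups, but 0.943 with an estimated correlation). With TMM scaling 5 immediate early genes rose and 1 fell, 2 NF-kB pathway genes rose and 0 fell, and 13 histone transcripts rose and 0 fell. Of the 5 measured genes of the NRF2 oxidative stress response 4 rose, among them the aldo-keto reductase gene AKR1B10 (22.1-fold) and SRXN1, which repairs oxidized peroxiredoxins (4.52-fold), and with TMM scaling 3 rose and 1 fell. The haematopoietic markers LAPTM5 and ITGAM rose by log2 4.36 and 4.15 (ITGAM 3.52 without DMSO replicate 3), and CD68 did not pass (1.13-fold, adjusted p = 0.584; 0.0231 without DMSO replicate 1; log2 −0.81 with TMM scaling, a fall that passed with an adjusted p of 0.0184).

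By limma 2076 genes were higher and 137 lower with MI-1061, and with TMM scaling, which moved the median log2 by −0.98, 942 were higher and 925 lower. Count tests on the recovered reads gave 1898 higher and 93 lower with edgeR, and 1953 higher and 105 lower with DESeq2. Here too the DMSO libraries take part in the listing, so the counts depend on it.

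MD-224 without NCS was compared with the same DMSO libraries. The p53 targets again rose, in 30 of 35 members (31 when adjusted over the list alone) with 0 falling, and a median of 2.41-fold, and with TMM scaling 24 rose and 1 fell. MDM2 rose 3.03-fold (SE 0.17 on the log2 scale; limma adjusted p = 2.4e-06), CDKN1A 7.67-fold, TP53INP1 5.65-fold and ZMAT3, an RNA-binding p53 target, 3.55-fold. Camera gave an adjusted p of 3.41e-12 for the list, and an adjusted p of 0.567 with an estimated correlation. Outside the list, HES2, a transcriptional repressor of the Hairy family, rose 24.5-fold (adjusted p = 3.56e-07), TMEM132B, a transmembrane protein gene, by log2 3.39, PTCHD4, a patched-domain protein gene, 9.03-fold, and PRMT8, an arginine methyltransferase, 8.17-fold. GRM8, a glutamate receptor gene, fell to 0.101-fold (adjusted p = 1.34e-06), RELT, a TNF receptor family gene, to 0.319-fold, and FGFR2 to 0.352-fold. With a pseudocount of 5 the log2 of HES2 (4.62) was 3.81 and that of GRM8 (−3.31) was −2.59, and without replicate 3 of every group that of TMEM132B was 2.73.

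Among immediate early and MAPK feedback genes 1 rose and 1 fell, the latter being FOSL1, an AP-1 subunit, at 0.415-fold (adjusted p = 0.000623). The list's median log2 was −0.05 and its mean 0.04. It stood below other listed genes by camera (adjusted p = 0.00982) but not with an estimated correlation (adjusted p = 0.773), nor with TMM scaling (0.106), where 0 rose and 4 fell, nor without DMSO replicate 2 (0.222) or MD-224 replicate 1 (0.0821), or without replicate 1 (0.134) or 2 (0.0824) of every group. Of the 8 NF-kB pathway genes 2 rose (0 when adjusted over the list alone) and with TMM scaling 0 rose and 2 fell. Of the 18 histone transcripts 10 rose, among them HIST1H2BG at 3.51-fold, and of 8 cytokine genes 5 rose, IL1B at 5.52-fold and CSF1, the macrophage growth factor, at 2.24-fold. With TMM scaling 3 histone transcripts rose and 2 fell, and 2 cytokine genes rose and 0 fell. Limma called 1225 genes higher and 86 lower, and with TMM scaling, a shift of the median log2 by −0.49, 327 higher and 357 lower. EdgeR called 822 higher and 45 lower, DESeq2 990 and 57. Without replicate 3 of every group 620 genes were called, and 809 with only the compared groups in the fit. The counts for MD-224 depend on the listing as well, since the DMSO libraries take part in it.

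MI-1061 was also compared with vehicle in cells already treated with NCS. Among the largest rises were SFN and DRAXIN. SFN, the 14-3-3 sigma protein that holds cells in G2, rose 125-fold (log2 6.96, SE 0.85; limma adjusted p = 1.35e-06; log2 6.25 without NCS and MI-1061 replicate 2), DRAXIN, an axon guidance protein, 121-fold, AREG, a ligand of the EGF receptor, 65.7-fold (adjusted p = 1.49e-09), and COL17A1, a collagen of hemidesmosomes, 60.9-fold. Every measured p53 target rose, 35 of 35, with a median of 5.42-fold. MDM2 rose 13.5-fold (log2 3.75, SE 0.17; adjusted p = 3.83e-11), CDKN1A 11-fold, FAS 8.2-fold and RRM2B, a ribonucleotide reductase subunit, 7.31-fold. With TMM scaling 31 p53 targets rose and 1 fell. Camera gave the list an adjusted p of 7.11e-14, and an adjusted p of 0.247 with an estimated correlation. Genes that fell included SMCO3, a membrane protein gene (0.305-fold), MYPN, a sarcomere protein gene (0.375-fold), and HSD3B7, an enzyme of bile acid synthesis (0.419-fold).

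The other groups moved unevenly. All 7 measured genes of the integrated stress response rose, among them PSAT1 (3.95-fold) and NUPR1 (5.97-fold), with a camera adjusted p of 0.519, and 3 rose with TMM scaling. Of the 8 cytokine genes 4 rose (2 when adjusted over the list alone), IL1B at 9.8-fold and IL1A at 7.76-fold, while with TMM scaling 2 rose and 4 fell. That list had a camera adjusted p of 0.0935, 0.0438 with the replicate number as a block, 0.0353 with a mean of at least 50, 0.0321 without replicate 2 of every group and 0.0162 with only the compared groups, and 0.554 with an estimated correlation. Histone transcripts rose in 5 of 18 members (4 when adjusted over the list alone), had a median of 1.15-fold and stood below other listed genes (camera adjusted p = 0.000326, 0.0593 with TMM scaling and 0.247 with an estimated correlation); HIST1H2BJ rose 16.6-fold, and with TMM scaling 2 members rose and 7 fell. Secreted proteases and growth factors rose in 9 and fell in 1 of 15 members, NF-kB pathway genes rose in 7 of 8 and immediate early genes in 8 of 12; with TMM scaling the medians of these 3 lists lay below 0, at −0.20, −0.10 and −0.45. Limma called 2168 genes higher and 23 lower, and with TMM scaling, a shift of the median log2 by −0.99, 733 higher and 593 lower. The libraries with NCS and MI-1061 are among those by which the genes are listed, so these counts depend on the listing.

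Several short lists had fewer members in the table, and their counts after NCS with MI-1061 were as follows. The 4 measured genes of the RNA polymerase III machinery all rose, with SNAPC1, a subunit of the complex that activates snRNA promoters, at 2.66-fold and GTF3C6, a TFIIIC subunit, at 2.06-fold, and with TMM scaling 0 rose and the list median was −0.06. Of these 4 genes 0 rose with NCS, 2 with MI-1061, 1 with MD-224 (0 when adjusted over the list alone) and 0 with MD-224 after NCS. With TMM scaling 0 rose and 2 fell with NCS, 1 rose and 2 fell with MI-1061, 0 rose and 1 fell with MD-224 and 0 rose and 0 fell with MD-224 after NCS. Both ribosome biogenesis genes rose, with POLR1A, the large subunit of RNA polymerase I, at 2.03-fold, and with TMM scaling 0 rose, while 4 of 5 genes of cholesterol synthesis rose, with HSD17B7 at 2.97-fold, and with TMM scaling 1 of these rose and the median was −0.35. Of 4 genes of MHC class I presentation 2 rose, with ERAP2, an antigen-trimming peptidase, at 2.04-fold, and with TMM scaling 0 rose and 2 fell. All 5 NRF2 genes rose, AKR1B10 at 6.2-fold, and with TMM scaling 2 rose and the median was −0.12. The osteoblast and bone matrix list rose in 3 of 5 members, BMP2 at 5.13-fold, and with TMM scaling 1 rose and 2 fell. Of the 5 measured neighbours of MDM2 in 12q13-q15, 3 rose, CPM at 7.23-fold, and with TMM scaling 1 rose and 1 fell. The epithelial marker CLDN4 rose 2.07-fold, a call lost with TMM scaling (log2 0.06, adjusted p = 0.882) and without replicate 3 of every group (0.136). Of the haematopoietic markers 2 of 3 rose (3 when adjusted over the list alone), LAPTM5 at 6.66-fold and ITGAM at 3.45-fold, and with TMM scaling 1.

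These short lists gave other counts with NCS, with MI-1061, with MD-224 and with MD-224 after NCS, given here in that order. Of the 5 genes of cholesterol synthesis 0, 4, 2 and 0 rose, of the 2 ribosome biogenesis genes 0, 1, 0 and 0, and of the 4 genes of MHC class I presentation 3, 3, 0 and 0. With TMM scaling 0 of these genes rose in any of the 4 comparisons, and 1 gene of each list fell with NCS and with MI-1061, as did 1 ribosome biogenesis gene with MD-224. Of the 5 osteoblast genes 5, 4, 2 and 1 rose, and with TMM scaling 1, 2, 0 and 0, with 1 falling with MI-1061. Of the 5 neighbours of MDM2 3, 4, 2 and 2 rose, and with TMM scaling 1, 2, 1 and 1, with 2, 1, 2 and 0 falling.

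With MD-224 after NCS fewer of these genes were called higher than with MI-1061 after NCS. The genes are listed by their rise with NCS and MI-1061, so this difference in counts cannot be separated from the listing. Of the 35 p53 targets 34 rose (35 when adjusted over the list alone) and 0 fell, with a median of 2.29-fold, and 27 rose with TMM scaling. MDM2 rose 4.53-fold (log2 2.18, SE 0.17; limma adjusted p = 3.51e-07), CDKN1A 4.73-fold (adjusted p = 1.44e-07), FAS 2.9-fold and RRM2B 2.91-fold. Camera gave the list an adjusted p of 7.63e-35, and this call held with an estimated correlation (adjusted p = 0.0293). Beyond the list, MYH16, a myosin heavy chain gene, rose 8.63-fold (adjusted p = 0.000545), TMEM40 7.98-fold, the transcription factor gene DACH2 7.21-fold and HES2 6.43-fold. Of the histone transcripts 1 of 18 rose, HIST1H2BJ at 2.49-fold, with a median log2 of 0.09, and with TMM scaling 1 rose and 1 fell, with a median of −0.23. That list stood below other listed genes by camera (adjusted p = 0.00511), but not with an estimated correlation (adjusted p = 0.499), with TMM scaling (0.0917), nor without NCS replicate 2 (0.126) or without NCS and MD-224 replicate 1 (0.0668). None of the 8 NF-kB pathway genes and none of the 12 immediate early genes passed by limma, with TNFAIP3 at 1.27-fold (adjusted p = 0.237).

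Limma called 465 genes higher and 0 lower with MD-224 after NCS, with 895 genes at an unadjusted p under 0.05. With the replicate number as a block it called 755 higher and 0 lower, and with TMM scaling 116 higher and 6 lower. The count fell without some single libraries, to 298, 287 and 283 without NCS replicate 1, 2 and 3, and to 186 without NCS and MD-224 replicate 1; it was 176 without replicate 1 and 163 without replicate 3 of every group.

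The inhibitor and the degrader were given at the same concentration and for the same 24 h, so they were compared directly. Without NCS the p53 targets were lower with MD-224 in 34 of 35 members, with a median of 0.433-fold, and with TMM scaling in 27, with 1 higher. MDM2 was at 0.262-fold (log2 −1.93, SE 0.17; limma adjusted p = 7.93e-08), CDKN1A at 0.255-fold, FAS at 0.253-fold and PPM1D, a phosphatase of the DNA damage response, at 0.231-fold. Camera gave the list an adjusted p of 6.97e-06, and an adjusted p of 0.646 with an estimated correlation. KRT78 was at 0.00951-fold, KRT4 at 0.0205-fold and TBX4 at 0.0143-fold, and ARC, a neuronal immediate early gene, at 0.0224-fold (adjusted p = 3.52e-09). Higher with MD-224 were HOGA1, an enzyme of hydroxyproline breakdown (11.8-fold, adjusted p = 2.33e-05), QPRT, an enzyme of NAD synthesis (7.13-fold), NKX2-8 (6.82-fold), SATB1, a chromatin organizer (4.5-fold), and the collagen gene COL1A2 (3.55-fold). The log2 of QPRT (2.83) was 2.21 without MI-1061 replicate 2, and without replicate 1 and 2 of every group it was 3.52 and 1.97, and that of HOGA1 (3.56) 4.39 and 2.87. KRT78 (log2 −6.72) was at −7.36 without replicate 1 of every group. FOSB was at 0.0854-fold, and 10 of 12 immediate early genes and 6 of 8 NF-kB pathway genes were lower, with 0 higher; the immediate early list had a camera adjusted p of 0.138, 0.646 with an estimated correlation and 0.174 with the replicate number as a block, but 0.0368 without MI-1061 replicate 1 and 0.0416 with TMM scaling, where 8 were lower and 1 higher. With TMM scaling 5 NF-kB pathway genes were lower. ITGAM and LAPTM5 were at 0.0489-fold and 0.129-fold.

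Limma called 381 genes higher and 1531 lower with MD-224 than with MI-1061, and with TMM scaling, a shift of the median log2 by 0.49, 847 higher and 941 lower. EdgeR called 277 higher and 1344 lower, DESeq2 318 and 1396. These 6 libraries are not those by which the listed genes stand out, but every listed gene rose with NCS and MI-1061, so the table favours genes that respond to MI-1061.

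After NCS the same comparison gave fewer genes higher with MD-224. Its libraries with NCS and MI-1061 are among those by which the genes are listed. The counts of higher and lower genes therefore cannot be separated from the listing. The p53 targets were lower in 34 of 35 members, with a median of 0.422-fold, and with TMM scaling in 20, with 1 higher. MDM2 was at 0.336-fold (log2 −1.57, SE 0.17; limma adjusted p = 9.5e-07), CDKN1A at 0.428-fold, FAS at 0.354-fold and TP53I3, an oxidoreductase, at 0.134-fold. Camera gave the list an adjusted p of 1.64e-07, and an adjusted p of 0.561 with an estimated correlation. PHACTR3, a regulator of phosphatase 1 and actin, was at 0.0272-fold (adjusted p = 6.86e-07), DRAXIN at 0.0327-fold, SFN at 0.0567-fold and AREG at 0.0767-fold. The log2 of DRAXIN (−4.93) was −4.25 without NCS and MD-224 replicate 3, and that of SFN (−4.14) was −3.39 without the same library and −3.43 without NCS and MI-1061 replicate 2. Higher were MYPN (3.07-fold, adjusted p = 0.00168), HSD3B7 (2.45-fold) and PAPPA, a protease that frees insulin-like growth factors (2.24-fold, adjusted p = 6.5e-06). Histone transcripts were lower in 5 of 18 members, with a median log2 of −0.20 (3 higher and 1 lower with TMM scaling, with a median of 0.46), but stood above other listed genes by camera (adjusted p = 0.0326, and 0.561 with an estimated correlation). That call was lost with TMM scaling (0.272), with a mean of at least 50 (0.084), without NCS and MI-1061 replicate 1 (0.0685) or without NCS and MD-224 replicate 2 (0.071). Limma called 23 genes higher and 1680 lower, and with TMM scaling, a shift of the median log2 by 0.66, 357 higher and 550 lower; 1080 were called without replicate 3 of every group.

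**Figure D2:**
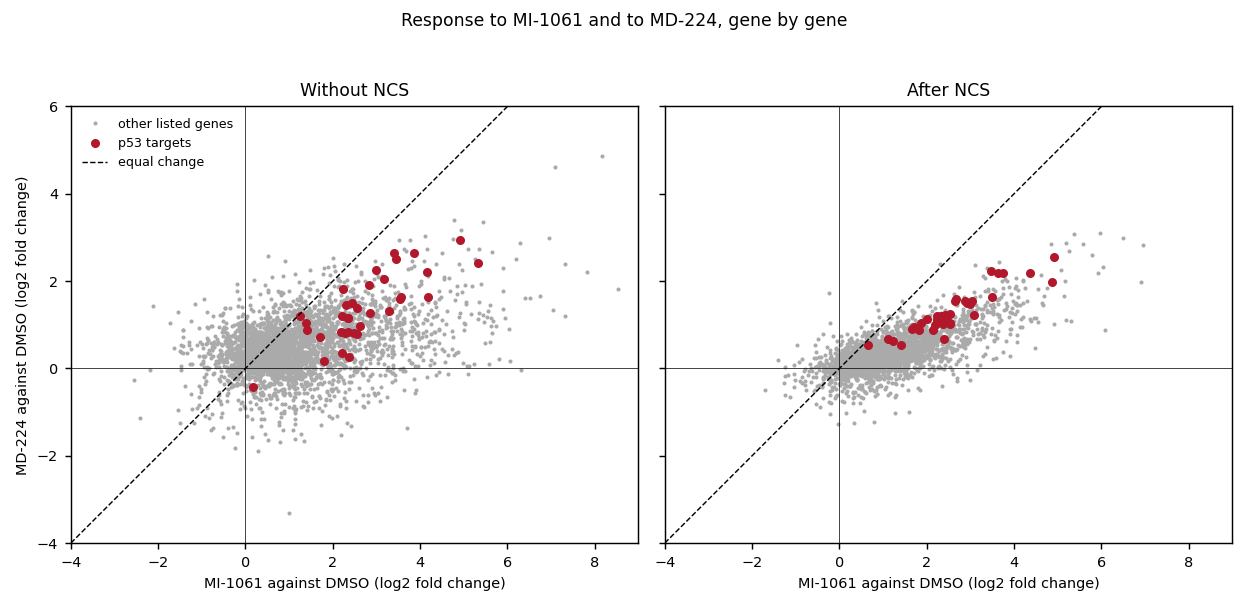
Log2 fold change with MD-224 (vertical) against that with MI-1061 (horizontal) for each tested gene, without NCS (left) and after NCS (right); red points are the p53 targets and the dashed line marks equal change. Most p53 targets lie above 0 on both axes and below the line, with median rises of 5.62-fold and 2.41-fold without NCS and 5.42-fold and 2.29-fold after NCS.

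Without NCS 931 genes were higher with both compounds, 76% of the 1225 higher with MD-224, where independent lists would share 827.6, and 18 were lower with both, where independent lists would share 3.834. After NCS 464 genes were higher with both, 99.8% of the 465, where independent lists would share 328.1. The compounds share their control libraries, and unchanged groups simulated against those controls shared 0 called genes. Without any change almost no gene is called, so this does not measure how far shared controls raise the overlap. The counts for independent lists leave out that the genes are listed by their rise with NCS and MI-1061. They are therefore no baseline for sharing by chance. Across genes, which are not independent replicates, the fold changes had a correlation of 0.398 without NCS (simulated 0.5) and 0.727 after NCS (simulated 0.499), and a covariance of 0.369 (simulated 0.0558) and 0.336 (simulated 0.0556). The 3 controls are too few to give each compound its own control libraries.

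Interferon-stimulated genes and sensors of cytosolic nucleic acids bear on the response named in the title. Of 39 interferon-stimulated genes 6 were in the table, and the listing leaves out the others. All 6 rose with NCS, beside 54% of all tested genes. They included STAT2, the transcription factor of interferon signalling (2.16-fold, limma adjusted p = 9.96e-07), and RSAD2, the antiviral protein viperin (9.69-fold, adjusted p = 0.00295). With TMM scaling 2 rose and 0 fell. The RSAD2 call was lost without replicate 3 of every group (adjusted p = 0.0781), and its log2 (3.28) was 2.61 and 4.27 without DMSO replicate 1 and 2, 3.91 without NCS replicate 1 and 2.64 with a pseudocount of 5. The list had a camera adjusted p of 0.199 with NCS, and 0.628 with an estimated correlation. With MI-1061 2 rose without NCS and 3 after NCS (2 when adjusted over the list alone), and with TMM scaling 1 rose and 3 fell without NCS and 1 rose and 1 fell after NCS. With MD-224 3 rose without NCS and 1 after NCS, and with TMM scaling 2 and 0. TRIM22, an antiviral gene, rose 5.42-fold with MI-1061 and 3.51-fold with MD-224, and 3.22-fold and 1.8-fold after NCS, the last with an adjusted p of 0.0743 with TMM scaling. STAT2 rose 1.77-fold with MI-1061, where its log2 with TMM scaling was −0.17, and 2.1-fold with MD-224. Between the compounds after NCS 1 member was higher and 2 lower with MD-224; with TMM scaling 3 were higher and 0 lower. The list did not pass camera (adjusted p = 0.053, and 0.561 with an estimated correlation), but had an adjusted p of 0.0173 with the replicate block, 0.00466 without NCS and MI-1061 replicate 2, 0.0186 without NCS and MD-224 replicate 1, and 0.0392 and 0.00272 without replicate 1 and 2 of every group.

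ISG15 (chromosome 1, 1013497 to 1014540), a ubiquitin-like antiviral protein, had means of 983.1 ± 190 with DMSO, 1274 ± 329 with MI-1061, 1536 ± 284 with MD-224, 1651 ± 360 with NCS, 2532 ± 921 with NCS and MI-1061 and 1942 ± 359 with NCS and MD-224. By limma it rose 1.67-fold with NCS (adjusted p = 0.0205), a call lost with TMM scaling (0.731) and without DMSO replicate 1 (0.0758), DMSO replicate 3 (0.052), NCS replicate 2 (0.095) or NCS replicate 3 (0.0505), and without replicate 3 of every group (0.176). Its rises with MD-224 (1.56-fold, adjusted p = 0.049) and with MI-1061 after NCS (1.49-fold, adjusted p = 0.0499) were at the threshold. The first was lost with TMM scaling (0.698), with edgeR (0.059), with a pseudocount of 5 (0.05) and without DMSO replicate 1 (0.15) or 3 (0.103) or MD-224 replicate 2 (0.166) or 3 (0.0919), and without replicate 1 (0.0536) or 3 (0.263) of every group. The other was lost without NCS replicate 1 (0.198) or 3 (0.0899) or without NCS and MI-1061 replicate 2 (0.292) or 3 (0.07), without replicate 2 (0.085) or 3 (0.187) of every group and with a pseudocount of 0.5 (0.0503), and its log2 with TMM scaling was −0.42. ISG15 with MI-1061 alone did not pass (1.28-fold, adjusted p = 0.21; 0.0171 with the replicate number as a block; log2 −0.63 with TMM scaling, a fall that passed with an adjusted p of 0.0382). The compounds did not pass the test of their difference in ISG15, with a log2 difference of 0.29 (95% interval −0.249 to 0.82) without NCS and −0.34 (−0.873 to 0.196) after NCS, but they did with TMM scaling without NCS (log2 0.78, adjusted p = 0.0132) and with the block after NCS (adjusted p = 0.0291). After NCS the difference had the other direction with TMM scaling, at log2 0.33, and did not pass. Of the sensors, TMEM173, which encodes STING, rose 1.87-fold with NCS (adjusted p = 0.0638 with TMM scaling) and 2.29-fold with MI-1061 after NCS (0.159), and 3 of 3 measured members of that list rose with MI-1061 after NCS, 0 with TMM scaling. Of these 3 genes 1 rose with NCS, 3 with MI-1061, 2 with MD-224 and 0 with MD-224 after NCS, while with TMM scaling 0 rose in all 4 and 1 fell with MI-1061. TMEM173 was lower with MD-224 than with MI-1061 after NCS (0.46-fold, adjusted p = 1.5e-06), while without NCS the log2 difference was 0.13 (95% interval −0.129 to 0.397), and 0.63 with TMM scaling (adjusted p = 0.000146).

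**Figure D3:**
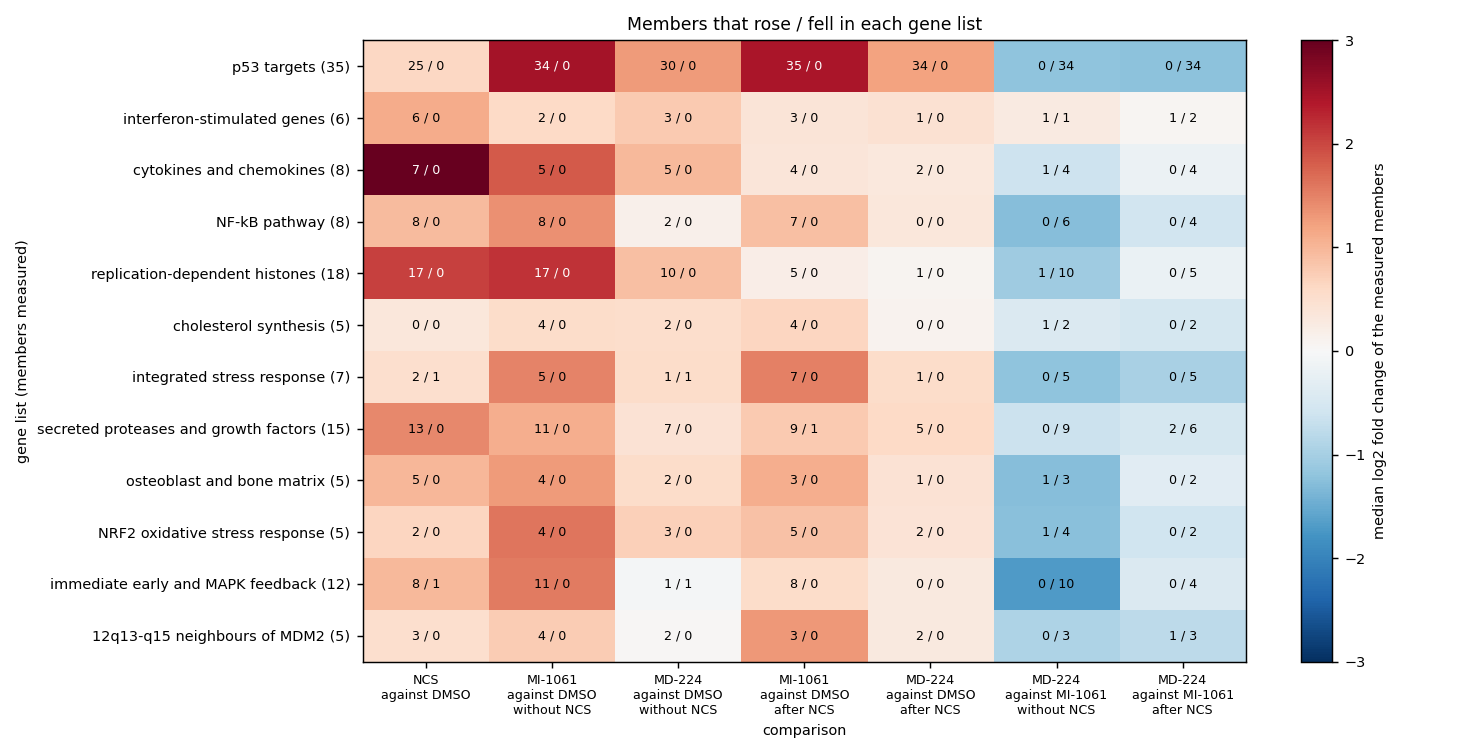
Median log2 fold change (color) of the measured members of 12 gene lists in 7 comparisons, with the numbers of members that rose and fell written in each cell as rose / fell. The p53 targets rose in 34, 30, 35 and 34 of 35 members with the compounds, and histones rose in 17 of 18 members with NCS and with MI-1061; with TMM scaling 34, 24, 31 and 27 p53 targets rose and 1, 1, 1 and 0 fell, and 14 and 13 histones rose.

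The interaction of NCS and MI-1061 asks whether the response to MI-1061 differed between cells with and without NCS. It was more positive after NCS for genes of different kinds. DERA, an enzyme of deoxyribose breakdown, had an interaction of log2 4.41 (SE 0.25; limma adjusted p = 2.05e-09), with means of 2214 with DMSO, 941 with MI-1061, 1347 with NCS and 11980 with NCS and MI-1061. NEMP2 had 4.37 (adjusted p = 2.05e-09), TMEM40 4.24 and DRAXIN 3.94. It was more negative for CEACAM20, an adhesion molecule (−6.94, adjusted p = 4.81e-07), FBXW10, an F-box protein (−6.58), KRT78 (−5.22) and TTN, the muscle protein titin (−4.96). FBXW10 had means of 4.725 with DMSO, 608.7 with MI-1061 and 12.95 with NCS and MI-1061. CDKN1A was more negative as well (−1.45, adjusted p = 6.98e-05), and MDM2 did not pass (0.22, adjusted p = 0.476). Of the 35 p53 targets 4 were more positive, TP53I3 at 2.04, and 7 more negative, PLK2, a polo-like kinase, at −1.05. Histone transcripts were more negative in 14 of 18 members, HIST1H4H at −2.50, and the list had a camera adjusted p of 0.000182, and 0.365 with an estimated correlation. IL6 was at −3.73 (adjusted p = 0.000895; −4.43 and −3.04 without DMSO replicate 2 and 3) and IL1A at 2.68 (adjusted p = 5.78e-05), and FOSB was at −2.97. With a pseudocount of 5 CEACAM20 was at −5.60 and FBXW10 at −5.85. Without replicate 1 of every group FBXW10 and KRT78 were at −5.64 and −6.21, FBXW10 was at −7.65 without replicate 2, and KRT78 at −4.52 without replicate 3. Limma called 721 genes more positive and 639 more negative, and 649 in all without replicate 3 of every group. The libraries with DMSO and those with NCS and MI-1061 both enter the listing, so these counts depend on it.

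**Figure D4:**
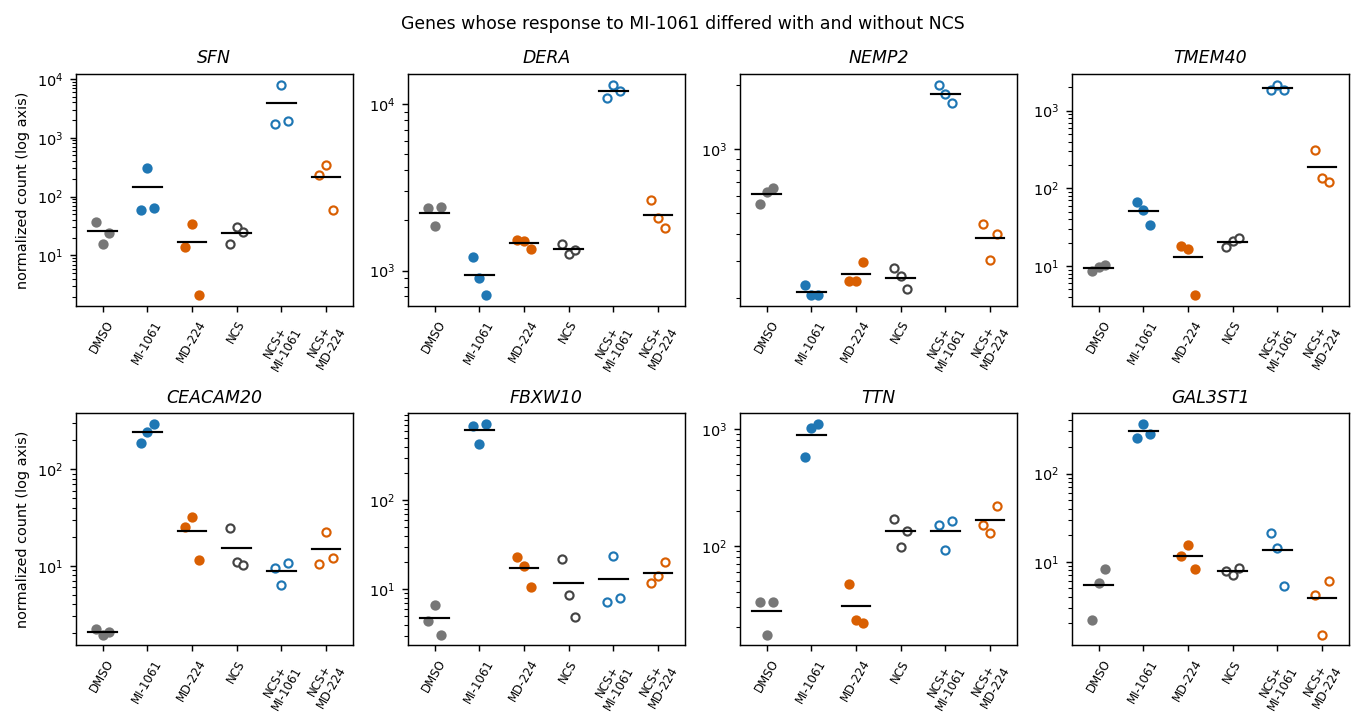
Normalized counts (log axis) of 8 genes named for the interaction of NCS and MI-1061, drawn as in the plot of MDM2, CDKN1A and other genes by group. DERA had a mean of 11980 with NCS and MI-1061 and 941 with MI-1061 alone, and FBXW10 had means of 12.95 and 608.7.

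The interaction of NCS and MD-224 was more positive for 125 genes and more negative for 221 by limma, and with TMM scaling, a shift of the median log2 by 0.16, for 201 and 127. The DMSO libraries enter the listing, so these counts depend on it too. GRM8 was at 4.26 (SE 0.46; adjusted p = 6.89e-05; 3.46 with a pseudocount of 5), with means of 52.41 with DMSO, 4.576 with MD-224, 34.42 with NCS and 68.2 with NCS and MD-224. TMEM132B was at −3.15 (adjusted p = 0.000743) and C5AR2, a receptor for complement C5a, at −3.03 (adjusted p = 0.00355), and both calls were lost without replicate 3 of every group (0.089 and 0.186, TMEM132B at −2.33). Of the 35 p53 targets 1 was more positive and 6 more negative, and with TMM scaling 5 and 3. Histone transcripts were more negative in 6 of 18 members and more positive in 1 (2 and 1 with TMM scaling), with a camera adjusted p of 0.053, and 0.825 with an estimated correlation. It was 0.0229 with the replicate number as a block, 0.0217 with TMM scaling, 0.0141 without DMSO replicate 2, 0.021 without MD-224 replicate 2, 0.0181 and 0.0484 without NCS replicate 1 and 3, 0.0421 and 0.0436 without NCS and MD-224 replicate 2 and 3, and 0.0094 without replicate 2 of every group. The count of 346 was 612 with the replicate number as a block (212 more positive and 400 more negative), 179 without MD-224 replicate 3, 182 and 172 without NCS replicate 2 and 3, 219 without NCS and MD-224 replicate 1, and 160, 178 and 4 without replicate 1, 2 and 3 of every group. Residuals permuted over the 12 libraries gave up to 480 genes.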

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

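The tests on the scaling and listing of genes and on histone transcripts in this part were chosen only after the results were seen, while the splits of libraries, the left-out MI-1061 libraries and the gene spans were planned before their results were seen. Several genes responded differently to a compound after NCS than without NCS, by the interaction tested in limma, and these values are log2 differences of responses. For MI-1061 they were −1.448 for CDKN1A, 4.871 for SFN, 4.407 for DERA, 4.367 for NEMP2, 4.239 for TMEM40 and 3.945 for DRAXIN. They were −6.94 for CEACAM20, −6.581 for FBXW10, −5.22 for KRT78, −5.116 for GAL3ST1 and −4.964 for TTN, and the histone list had a median of −1.62. SFN was lost without replicate 1 of every group (adjusted p = 0.0624), and was 5.64 without MI-1061 replicate 2 and 4.16 without NCS and MI-1061 replicate 2. With a pseudocount of 5 CEACAM20, FBXW10 and GAL3ST1 were −5.60, −5.85 and −4.46. For MD-224 they were 4.265 for GRM8, 3.919 for SFN, 2.853 for COL17A1, 2.813 for AREG and 2.791 for TMEM40. They were −0.6984 for CDKN1A, −3.171 for LGR6, −3.155 for TMEM132B, −3.031 for C5AR2, −2.855 for CEACAM20 and −2.832 for KLHL38. All of these for MD-224 but GRM8 were lost without replicate 3 of every group, with adjusted p values of 0.0663 for AREG to 0.489 for CDKN1A.

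Of the MD-224 results, 4 were also lost without single libraries, with these adjusted p values. CDKN1A (0.0484) had 0.0545 and 0.104 without DMSO replicate 2 and 3, 0.094, 0.0558 and 0.0764 without MD-224 replicate 1, 2 and 3, 0.104, 0.0681 and 0.0995 without NCS replicate 1, 2 and 3, 0.116 without NCS and MD-224 replicate 2 or 3, and 0.104 with TMM scaling. SFN (0.0452) had 0.0918 and 0.0693 without DMSO replicate 1 and 3, 0.0527 and 0.12 without MD-224 replicate 1 and 3, 0.0906, 0.0756 and 0.0832 without NCS replicate 1, 2 and 3, and 0.0999 and 0.102 without NCS and MD-224 replicate 1 and 2. COL17A1 (0.0417) had 0.09 without DMSO replicate 1, 0.0517 and 0.112 without MD-224 replicate 2 and 3, 0.0811, 0.0733 and 0.0855 without NCS replicate 1, 2 and 3, and 0.098 and 0.0813 without NCS and MD-224 replicate 1 and 2. KLHL38 (0.023) had 0.0617 without MD-224 replicate 3, 0.0558 and 0.0533 without NCS replicate 2 and 3, and 0.0606 without NCS and MD-224 replicate 3. Without replicate 1 of every group AREG, TMEM40, LGR6, CEACAM20, SFN and COL17A1 had 0.0918, 0.0559, 0.163, 0.112, 0.273 and 0.247, and without replicate 2 TMEM40, COL17A1, KLHL38 and CDKN1A had 0.0507, 0.0509, 0.101 and 0.145. Some log2 values moved by over 1.5-fold without a single library: COL17A1 to 2.05 and KLHL38 to −1.96 without DMSO replicate 1, LGR6 to −3.87 without DMSO replicate 2, KLHL38 to −3.44 without DMSO replicate 3, SFN to 4.72 without MD-224 replicate 2, SFN to 2.95 and TMEM40 to 2.18 without MD-224 replicate 3, and SFN to 4.67 without NCS and MD-224 replicate 3. With a pseudocount of 5 GRM8, LGR6 and CEACAM20 were 3.46, −2.47 and −1.91. With only the compared groups in the fit CDKN1A, SFN, COL17A1 and KLHL38 had 0.1, 0.055, 0.0602 and 0.0602.

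Most listed genes were lower with MD-224 than with MI-1061 without NCS. The listing of genes by their rise with NCS and MI-1061 might produce this, but the p53 targets, of which 35 of 38 are listed, had a median log2 difference of −1.21. By sign alone 35 of 35 were lower, and 34 passed by limma. Unequal size factors might produce it too. With the shared shift taken out by TMM the p53 median was −0.709, with 27 lower and 1 higher by limma. Over all tested genes the same scaling gave 847 higher and 941 lower, with a median log2 of −0.08. Size factors are thus argued against for the p53 targets alone, and they stay open for the other genes. The listing stays open for the other genes as well. The 1204 genes that rose with NCS alone by the listing fold had a median of −0.796, yet they too are listed by their level with MI-1061. A weaker effect of the degrader stays open and was not tested, since each compound was given at 1 concentration and for 1 time.

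Of the 2076 genes that rose with MI-1061, 226 (10.9%) met 2 conditions. Their interaction of NCS and MI-1061 was negative with an adjusted p under 0.05 by limma. They were also at least 2-fold lower with NCS and MI-1061 than with MI-1061 alone (smallest difference 2.01-fold). Among them were FBXW10, CEACAM20 and GAL3ST1. At least 92% of these genes stayed at least 2-fold lower without any 1 of the 3 MI-1061 libraries. The genes were chosen by tests on the same 3 libraries, which favour genes high in all of them. This therefore cannot decide whether a single aberrant library plays a part. Size factors are argued against, since the p53 targets moved the other way, with a median log2 of 0.576 and 30 of 34 higher. Less transcription of long genes after DNA breaks was tested by gene spans. The median was 23.2 kb for these genes and 28 kb for the others that rose (ratio 0.829, one-sided permutation p = 0.946 for longer spans). Among listed genes the pattern thus did not fall on longer genes. Genes that NCS with MI-1061 left unchanged or lowered are not listed, so an effect of length on those cannot be judged. An effect of NCS on these genes themselves stays open and was not tested.

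Histone transcripts rose with NCS in 17 of 18 members. Looser selection of poly(A) RNA in the NCS libraries was tested by how unequal the folds were, with a chi-square over its degrees of freedom of 8.31 for the 18 genes. The condition first written took a value above 2 as excluding it. That was wrong, and it was changed after the value was seen: genes differ in how much of their RNA carries a poly(A) tail, so unequal folds exclude nothing. A further test, of read sharing between histone copies, was dropped after its result was seen. The technical explanation and a change in polyadenylation or cell cycle with NCS cannot be told apart here.

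The 6 libraries of a pairwise comparison make 10 splits into 3 and 3, too few for a share under 0.05, and in each comparison 1 split, the real one, gave as many genes. The highest other split gave 0 genes in NCS against DMSO (1699), MI-1061 against DMSO without NCS (2213) and after NCS (2191), MD-224 after NCS (465) and MD-224 against MI-1061 without (1912) and after NCS (1703), and 31 in MD-224 without NCS (1311). For the interaction with MI-1061, 1 of 100 permutations of residuals, the real one included, gave as many as 1360 genes, with 477 the highest other. For that with MD-224, 2 of 100 gave as many as 346, with 480 the highest other. Both shares lie under 0.05, but the permutations ignored the replicate numbers and took all libraries as exchangeable, so they are approximate. For MD-224 a permutation gave more genes than the real one, and 4 genes were called without replicate 3 of every group. Chance is therefore not excluded for MD-224.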

How the results depend on the processing

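All alternatives in this part were planned, and none was chosen only after the result was seen. Over the 9 counts of called genes, 76 of the values with left-out libraries and 60 of the others stayed within 1.5 times the reported count, and 17 and 9 did not. Of the 171 gene results named in the text, 139 kept direction and side of the threshold under every alternative run. With left-out libraries the counts ranged over 902 to 1597 for NCS against DMSO, 620 to 1227 for MD-224 without NCS, 163 to 463 for MD-224 after NCS, 1080 to 1630 for MD-224 against MI-1061 after NCS, 649 to 1391 for the interaction with MI-1061 and 4 to 412 for that with MD-224. Fewer libraries enter these fits, and the lowest counts were all without replicate 3 of every group.

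With TMM scaling the counts were 923 for NCS, 684 for MD-224 without NCS, 1326 for MI-1061 after NCS, 122 for MD-224 after NCS and 907 for MD-224 against MI-1061 after NCS. TMM takes out a shared shift, which moved the median log2 by −0.604, −0.488, −0.988, −0.325 and 0.662 in these comparisons, and it turned the sign of MDM2 with NCS (−0.1653), of ISG15 (−0.6332), STAT2 (−0.1687) and CD68 (−0.8106) with MI-1061, and of ISG15 with MI-1061 after NCS (−0.4161). It also turned that of ISG15 between the compounds after NCS (0.3281), which passed neither with TMM scaling nor without it. With the replicate block 755 genes were called for MD-224 after NCS and 612 for the interaction with MD-224, and MD-224 without NCS gave 809 with only the compared groups and 867 with edgeR; the cause was not tested. With an estimated correlation the p53 targets had adjusted p values of 0.716 and 0.567 with MI-1061 and MD-224 without NCS, 0.247 with MI-1061 after NCS, and 0.646 and 0.561 between the compounds without and after NCS. With NCS they had 0.87 with an estimated correlation, and 0.0453 (without DMSO replicate 2) to 0.482 with left-out libraries. Interferon-stimulated genes between the compounds after NCS had adjusted p values of 0.0406 with a pseudocount of 5, 0.0446 with a mean of at least 50, 0.0173 with the block, 0.0197 with only the compared groups and 0.00272 to 0.239 with left-out libraries; the cause was not tested. Leaving out the filter adds 1 gene and tests nothing. EdgeR and DESeq2 were not run for comparisons with NCS libraries, where reads were not recovered in 5 libraries. Depth over all genes is unknown, and for genes with few counts the part of counting error in the spread was not measured.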

Other observations

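The tests in this part were all chosen only after the results were seen, with gene lists written from themes noticed among the listed genes. Their p values therefore describe these themes and are no independent test of them. Lysosomal genes encode the enzymes and membrane proteins of the degradative compartment. Of 53 such genes 32 were listed, and by limma 29 rose with NCS, 29 with MI-1061, 27 with MD-224, 26 with MI-1061 after NCS and 7 with MD-224 after NCS. With TMM scaling 8 rose and 2 fell with NCS, 7 rose and 11 fell with MI-1061, 3 rose and 1 fell with MD-224, 0 rose and 20 fell with MI-1061 after NCS, and 0 rose and 0 fell with MD-224 after NCS. CTSD, which encodes the protease cathepsin D, rose 1.9-fold with NCS, 2.67-fold with MI-1061 and 1.83-fold with MD-224. The hypothesis that lysosomal genes rose more than other listed genes gave camera p = 1.26e-05 with NCS (p = 0.0263 with an estimated correlation), p = 0.00389 with MI-1061 (0.12) and p = 1.05e-05 with MD-224 (0.0252). With MI-1061 after NCS the p was 0.905 (0.946). Camera compares moderated statistics rather than folds. The list's median log2 was 0.69, 0.93 and 0.60 in the first 3 comparisons, and that of all genes was 0.66, 1.00 and 0.48. With MI-1061 the median fold was thus not larger than that of other listed genes.

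Genes of stratified epithelia were listed for 20 of 44 members. By limma 11 rose with NCS, 17 with MI-1061 and 20 with MI-1061 after NCS. With MD-224 3 rose without NCS and 7 after NCS (10 when adjusted over the list alone). With TMM scaling 6 rose and 3 fell with NCS, 9 rose and 2 fell with MI-1061, and 10 rose and 0 fell with MI-1061 after NCS. The same scaling gave 3 that rose and 1 that fell with MD-224, and 2 and 1 with MD-224 after NCS. Camera gave p = 0.0926 (0.295 with an estimated correlation) with MI-1061 and p = 0.00383 (0.0839) with MI-1061 after NCS. Genes of striated muscle were listed for 12 of 37 members. With MI-1061 8 rose and 2 fell, with and without TMM scaling. With MI-1061 after NCS 4 rose and 2 fell, and with TMM scaling 1 rose and 4 fell. With NCS alone, the control of that comparison, 8 rose and 0 fell, and with TMM scaling 7 rose and 0 fell. With MD-224 5 rose and 2 fell, and with TMM scaling 0 rose and 2 fell. With MD-224 after NCS 1 rose and 0 fell, with and without TMM scaling. Camera gave p = 0.663 with MI-1061 (0.753 with an estimated correlation). With MI-1061 after NCS the list stood below other listed genes with camera p = 0.00166 (0.0381 with an estimated correlation), opposite to the hypothesis that it rose more.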
